A study of Rattus norvegicus with 1008 samples.

How the data were processed

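Gene expression was measured in 12 tissues of male and female Sprague Dawley rats with TempO-Seq, a targeted RNA sequencing assay in which pairs of detector oligonucleotides are ligated on their target transcript, amplified and sequenced. The rat S1500+ panel gave 2654 probes for 2603 genes, and 35 genes had more than 1 probe. Each library is 1 tissue of 1 animal. The 96 animals were separate, so the spread within a group is that between animals.

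The deposited values are counts, whole numbers of reads per probe and library with no scaling, per the labels' protocols and the values themselves. The submitters' processing notes name HISAT2 as the aligner. Its version, the genome build, the counting tool and any filter on reads are not given in the sources used here, and no genome was used here. The authors deposited 1 table for each of the 21 sets of tissue and sex, and columns were matched to animals by their names. The tables hold the probe names as a list beside the counts and no name on each line of counts, so the names were taken to follow the order of the lines, and 17 names written with a dot were matched by their number. This order was checked with marker lists of cell types. In 9 of 9 lists the tissue that the list stands for was highest, against at most 3 over 200 random orders. The assay counts a short ligated stretch of each transcript, so probes for near-identical genes, such as Cyp2b1 and Cyp2b2 or Cyp4a family members, can share reads.

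Of 1008 libraries, 15 carried a quality issue in the labels and were left out. In 9 of these the label names an outlier, in 3 too small a part of reads aligned and in 3 too few probes were covered. Group sizes were then 8 vehicle animals and 5 animals at 100 mg/kg/day, except 7 and 4 in male heart and male testis and 8 and 4 in female spleen. The libraries left out had total counts from 84567 to 2901100. All 2203 pairs of libraries of the same group were compared by a chi-square test over probes, and the lowest chi-square per degree of freedom was 4.05 (median 36.0), so no library was taken as a repeat of another.

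Probes were tested with edgeR (version 4.0.16, in R 4.3.3), with TMM scaling, filterByExpr on the dose groups and the quasi-likelihood test. All 9 groups of a set entered 1 model with a coefficient per dose and shared the estimate of the spread. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over the probes tested in that set and contrast. The difference between the sexes was tested as the interaction of sex and dose in a model of the vehicle and 100 mg/kg/day libraries of a tissue. Means and SDs in the text are of CPM after TMM scaling, and log2 fold changes are those of the edgeR fit. Their SE is the size of the change divided by the root of the quasi-likelihood F.

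Genes were grouped in 41 lists written before the data were examined, 22 of pathways and 19 of cell types. A list with at least 5 measured probes was tested with camera of limma (version 3.58.1) on voom values, with a preset correlation of 0.01 between genes and again with an estimated one. The p-values were adjusted over the lists of a set. Members were counted as higher or lower from the edgeR calls, and again with the p-values adjusted over the list alone. Called lists are printed with their values or, in sets with few called probes, mostly as counts.

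The genes named were chosen by a rule. In the 3 sets with the most calls at 100 mg/kg/day (male spleen, male liver and female kidney) they were the 8 largest rises and 8 largest falls among called probes whose libraries lay on opposite sides of the midpoint of both group means, with at most 1 exception, and the 3 called members with the smallest p of each list called in camera. In every other set they were the 2 largest rises and 2 largest falls. Only probes with a mean of at least 5 CPM were named, with 1 probe per gene. For the difference between the sexes they were the 3 called probes with the smallest p per tissue. In liver of both sexes a fixed set of PPAR-alpha, nuclear receptor and stress genes is given whatever its p (Cpt1a did not pass the filter in either sex). A few genes that were chosen are not reported here, and no others took their place. Genes outside this rule are said to be chosen after their values were seen.

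Benchmark doses were fitted to log2 CPM (prior count 2) by least squares over linear, power (exponents 1.5, 2 and 3) and Hill curves (exponents 1, 2 and 4, midpoint from 0.003 to 300 mg/kg/day), and the curve with the lowest AIC was kept. The benchmark response was 1 SD pooled within groups. Probes entered if any dose was called by the F test over the 8 coefficients and some dose differed by at least 1.5-fold. They were kept if the lack-of-fit p was at least 0.1, the benchmark dose lay between 0.001 and 100 mg/kg/day and the upper bound of its 90% interval was at most 40 times the lower. A set with fewer than 10 kept probes has no median. The 95% interval of a median was taken from the order of the values of the kept probes. It treats probes as independent and does not measure the spread between animals.

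Animal numbers run in blocks of 8 animals per sex, and the dose groups fill them in order. The blocks are inferred from the numbers and are not in the labels. Vehicle animals form block 1 and no dosed animal lies in it, and block 6 holds 3 animals at 30 and 5 at 100 mg/kg/day. Over dosed animals the logarithm of total counts followed the block, with R2 from 0.706 to 0.985 in the female sets and from 0.0805 to 0.892 in the male sets. Dose gave 0.17 to 0.868 in the male sets, and more than the block in 6 of them. The comparison of 100 with 30 mg/kg/day inside block 6 was therefore made after seeing the data, and so was that of 10 with 30 mg/kg/day inside block 5. Both came from an edgeR fit of all libraries of a set with a coefficient for each dose in each block. For the difference between the sexes inside block 6, the animals of that block were fitted alone.

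Only fits of liver were tested on simulated data, not that of block 5 or of the sexes inside block 6. In simulated male liver counts (1991 probes) the comparison of 100 mg/kg/day with vehicle called 25.4% of changed probes at 1.5-fold, 50.7% at 2-fold and 75.8% at 4-fold, and 2.88% of its calls were unchanged probes. The comparison inside the block called 8.96%, 28.4% and 69.7%, and that of the sexes in liver 4.48%, 11.9% and 60.6%. These rates may not hold where blocks differ. The fitted benchmark dose had a median ratio of 1.02 to the true one over 58 probes, and 81.0% of intervals held it.

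Alternatives were DESeq2's size factors in the same edgeR fit, DESeq2 (version 1.42.0) with its Wald test, no filter on low counts, the counts of all probes of a gene summed, vehicle and 100 mg/kg/day libraries alone, all libraries kept, leaving out each animal in turn, an estimated correlation in camera, and a benchmark response of 2 SD or a fold filter of 2. For each count of calls, 40 splits of the same animals into groups of the same sizes, the real one included, were fitted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.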

Results

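Transcription was measured in rats given perfluorohexanesulfonamide, a fluorinated sulfonamide of the per- and polyfluoroalkyl substance class, to find the tissues and the doses at which gene expression responds to a short exposure. Sprague Dawley rats of both sexes were dosed by oral gavage over 5 days. Each sex held 8 vehicle animals and 5 animals at each of 8 doses, which were 0.01, 0.1, 0.3, 1, 3, 10, 30 and 100 mg/kg/day. Adrenal gland, brain, heart, kidney, liver, lung, spleen, thymus and thyroid were taken from both sexes, ovary and uterus from females, and testis from males. The 96 animals gave 21 sets of tissue and sex with 48 libraries in each. The files held whole-number counts for 2654 probes of 50 bases, which stand for 2603 genes. Of 1008 libraries, 993 carried no quality issue in the labels and were used. Their total counts lay between 198417 and 3840204 with a median of 1284000, and male liver averaged 3275297 ± 487401 (SD, n = 8) in vehicle animals and 2357331 ± 296520 (SD, n = 5) at 100 mg/kg/day.

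To ask which tissues responded to the highest dose, each set was compared with its own vehicle animals. Male spleen and male liver showed the largest numbers of changed transcripts, followed by female kidney, female thyroid and male testis. In male liver and male kidney the transcripts of fatty acid oxidation rose together. In female thyroid the transcripts of macrophages and of inflammation rose, but the count of calls was 5 without animal r94, against 110, and neither list passed with an estimated correlation (adjusted p = 0.42 and 0.462). In edgeR at a Benjamini-Hochberg adjusted p under 0.05, 406 probes were called in male spleen (170 higher, 236 lower), 234 in male liver (126 higher, 108 lower), 143 in female kidney (125 higher, 18 lower), 110 in female thyroid (103 higher, 7 lower) and 104 in male testis (34 higher, 70 lower). Male kidney had 39 calls (29 higher, 10 lower), male lung 26 (13 higher, 13 lower) and female liver 12 (9 higher, 3 lower). Each of the other 13 sets had between 1 and 8 calls. Animal numbers fell into 6 blocks of 8 consecutive animals per sex, and total counts followed these blocks in all female sets (R2 from 0.706 to 0.985 over dosed animals, and from 0.536 to 0.848 for dose). All vehicle animals formed block 1, so a change against vehicle cannot be told apart from a difference between blocks. For this reason the 5 animals at 100 mg/kg/day were also compared with the 3 animals at 30 mg/kg/day that shared the last block, and that within-block value is given for many of the genes named below.

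**Figure D1:**
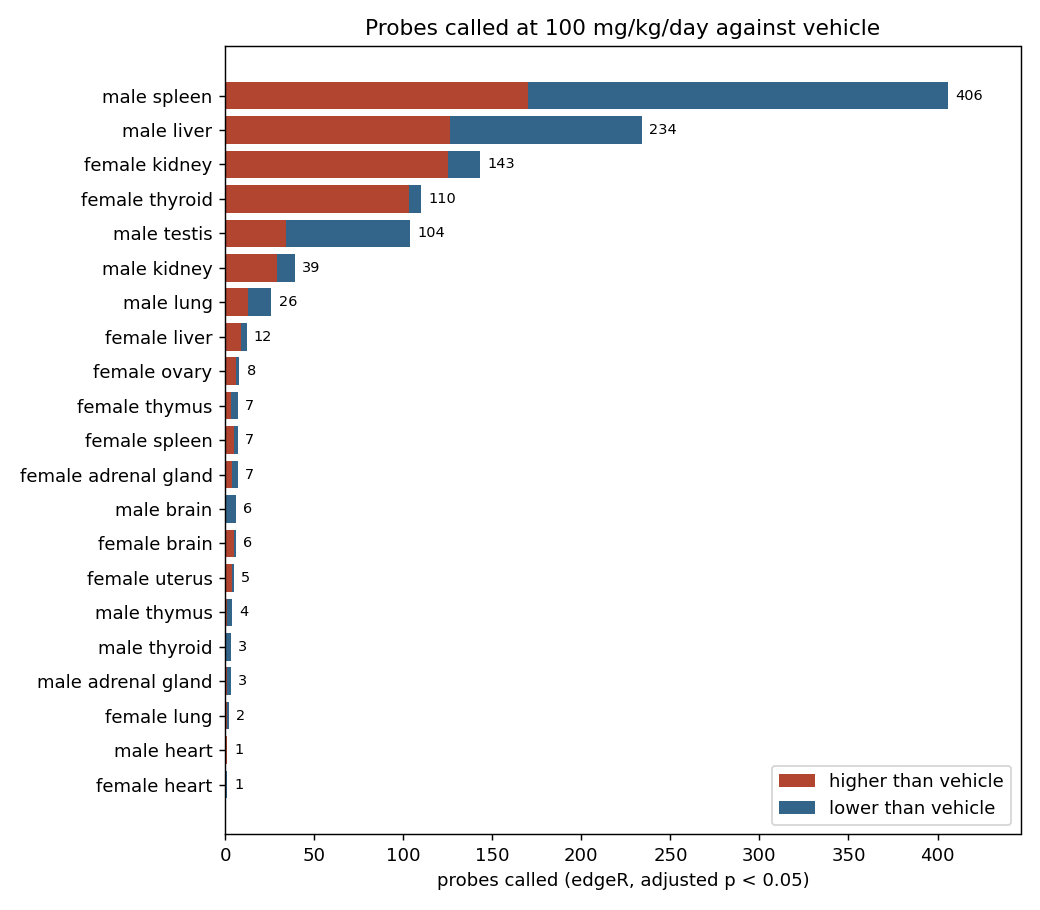
Probes called in edgeR at an adjusted p under 0.05 at 100 mg/kg/day against vehicle, with a bar for each of the 21 sets of tissue and sex, split into higher (red) and lower (blue). The bars run from 1 probe in male heart and in female heart to 234 in male liver and 406 in male spleen.

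In male liver, enzymes of drug metabolism and of fatty acid oxidation rose at 100 mg/kg/day. The largest change was in Cyp2b1, a cytochrome P450 induced through the constitutive androstane receptor. Its level went from 26.6 ± 11.4 CPM (SD, n = 8) in vehicle animals to 1816 ± 1545 CPM (SD, n = 5), a 68.5-fold rise. Cyp4a1, the fatty acid omega-hydroxylase that marks PPAR-alpha activity in rat liver, rose from 115 ± 19.8 CPM (SD, n = 8) to 688 ± 343 CPM (SD, n = 5). Ehhadh, the bifunctional enzyme of peroxisomal oxidation, rose from 84.9 ± 26.5 CPM (SD, n = 8) to 474 ± 397 CPM (SD, n = 5). For each of these genes all 5 animals lay above all 8 vehicle animals. Of 30 measured probes for PPAR-alpha targets, 16 rose, 0 fell and 14 did not pass (17 rose and 1 fell when adjusted over the list alone). In limma's camera the list rose with an adjusted p of 9.67e-11, and adjusted p = 0.00776 with an estimated correlation. Of 19 probes for targets of the nuclear receptors CAR and PXR, 10 rose, 1 fell and 8 did not pass (10 and 1 when adjusted over the list alone), with an adjusted p of 3.06e-06 in camera, and adjusted p = 0.00776 with an estimated correlation.

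The log2 fold changes in male liver at 100 mg/kg/day were 6.10 (SE 0.46, edgeR adjusted p = 4.29e-14) for Cyp2b1, 2.58 (SE 0.27, adjusted p = 1.57e-09) for Cyp4a1 and 2.48 (SE 0.27, adjusted p = 2.51e-09) for Ehhadh. Eci1, an isomerase of fatty acid oxidation, rose by 2.17 (SE 0.23, adjusted p = 1.57e-09), and Ech1, another such isomerase, by 2.28 (SE 0.26, adjusted p = 1.01e-08). Cyp2c6v1 rose by 2.04 (SE 0.24, adjusted p = 2.65e-08), Cyp2b2 by 1.55 (SE 0.17, adjusted p = 2.51e-09) and Cyp3a23-3a1 by 1.57 (SE 0.30, adjusted p = 0.000457). Inside the last block Cyp2b1 differed from 30 mg/kg/day by 3.80 (edgeR adjusted p = 0.000298), Cyp4a1 by 2.03 (0.000268), Eci1 by 1.66 (0.00256), Ech1 by 1.75 (0.00627), Ehhadh by 1.82 (0.00963) and Cyp2b2 by 1.09 (0.0118). Hsdl2, a peroxisomal dehydrogenase chosen after its values were seen, was the 7th and last probe called inside the block, at 1.70 there (0.0104) and 1.67 against vehicle. In the within-block comparison 13 PPAR-alpha probes were higher and 1 lower at an unadjusted p under 0.05, as were 5 higher and 0 lower of the CAR and PXR probes. At 30 mg/kg/day the change against vehicle was 1.99 for Cyp2b1, 0.64 for Cyp4a1 and 0.69 for Ehhadh. Nfkbie, an inhibitor of NF-kB (2.65), Pafah1b3 (2.60), RT1-DA, a class II histocompatibility gene (2.24), and the mitotic kinase Plk1 (2.24) also rose, and their within-block values were 1.37, 0.34, 0.76 and 1.41. Cyp1a1, a target of the aryl hydrocarbon receptor, rose from 4.84 ± 2.94 to 19.1 ± 5.81 CPM (SD, n = 8 and 5; edgeR adjusted p = 0.033), with a within-block value of 0.29. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.24, adjusted p = 0.0924), Cdkn1a (1.63, 0.168), Fasn (0.09, 0.872) and Nqo1 (-0.22, 0.831) did not pass in edgeR. Leaving out animal r44 lowered the count in male liver from 234 to 143 probes and ended the call of RT1-DA (1.88 without it), and the call of Cyp1a1 ended without any 1 of 8 animals (r01, r03, r04, r05, r07, r44, r45 or r48).

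**Figure D2:**
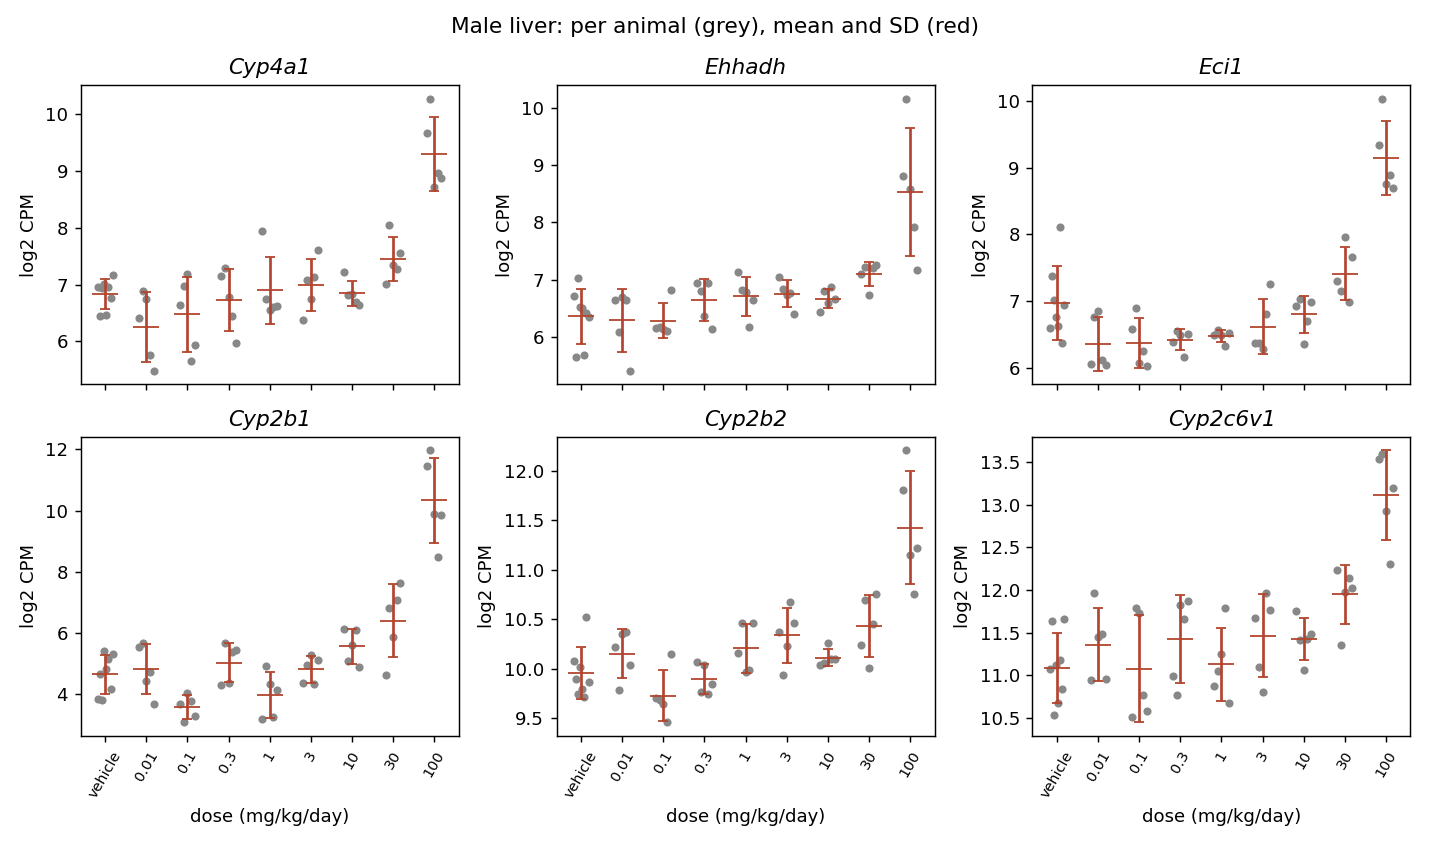
Level (log2 CPM) of Cyp4a1, Ehhadh, Eci1, Cyp2b1, Cyp2b2 and Cyp2c6v1 in male liver by dose (mg/kg/day), with 1 grey point per animal and the mean and SD of each group in red. The 100 mg/kg/day animals lie above all vehicle animals in each of the 6 genes, and Cyp2b1 was 1.99 above vehicle at 30 mg/kg/day and 6.10 above at 100 mg/kg/day.

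Transcripts that fell in male liver at 100 mg/kg/day included those of proteins the liver secretes into plasma. Apoa1, the main protein of high-density lipoprotein, fell from 86300 ± 36250 CPM (SD, n = 8) to 26693 ± 5025 CPM (SD, n = 5). Ahsg, a plasma glycoprotein, fell from 9346 ± 1648 CPM (SD, n = 8) to 3279 ± 695 CPM (SD, n = 5). All 5 animals lay below all 8 vehicle animals for both genes. Of 17 probes for acute phase and complement proteins, 0 rose and 7 fell (8 fell when adjusted over the list alone), with camera adjusted p = 0.006, and adjusted p = 0.313 with an estimated correlation. They included A2m (-1.83), Fgg (-1.05) and Fga (-0.92), which encode a protease inhibitor and chains of fibrinogen. Of 13 hepatocyte marker probes, 2 rose and 8 fell (2 and 10 when adjusted over the list alone), with camera adjusted p = 0.00483, and adjusted p = 0.134 with an estimated correlation. Among the rises was Cps1, the first enzyme of the urea cycle, at 143 ± 127 and 635 ± 152 CPM (SD, n = 8 and 5), but this probe already stood 2.54 above vehicle at 0.01 mg/kg/day.

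In edgeR the log2 fold changes of these falling genes in male liver were -1.69 (SE 0.23, adjusted p = 5.63e-07) for Apoa1 and -1.51 (SE 0.24, adjusted p = 1.06e-05) for Ahsg. Coagulation factor F5 (-1.60), plasminogen Plg (-1.51) and haptoglobin Hp (-1.73) fell as well, as did the transcription factor Foxo3 (-2.44), the DNA ligase Lig4 (-2.20), Rae1 (-1.88) and the immediate early gene Ier2 (-1.81). Within the last block none of these probes passed in edgeR. There Apoa1 stood at -0.49, Ahsg at -0.52, F5 at -0.68, Plg at -0.60, Hp at -0.84, Foxo3 at -1.88, Lig4 at -1.30, Rae1 at -0.67 and Ier2 at -2.01, while Cps1 stood at -0.35. Without r44 Lig4 stood at -1.99 and did not pass. Apoa1 was at -1.04 against vehicle at 10 mg/kg/day and at -1.18 at 30 mg/kg/day.

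In female liver few transcripts changed at 100 mg/kg/day. Orm1, an acute phase glycoprotein, rose from 2580 ± 1037 CPM (SD, n = 8) to 10321 ± 11975 CPM (SD, n = 5), and App, the amyloid precursor protein, rose from 31.1 ± 11.9 to 103 ± 27.5 CPM (SD, n = 8 and 5). Apoa1 fell from 67217 ± 12649 to 34773 ± 9663 CPM (SD, n = 8 and 5), and Noc2l, a nucleolar protein, fell from 34.8 ± 8.74 to 3.3 ± 1.56 CPM (SD, n = 8 and 5). Cyp2b1 had 3.53 ± 1.94 CPM (SD, n = 8) in vehicle animals and 19.9 ± 23.8 CPM (SD, n = 5) at 100 mg/kg/day and did not pass (log2 fold change 2.48, SE 0.65, edgeR adjusted p = 0.0536), with 4 of 5 animals above all vehicle animals. Cyp4a1 had 183 ± 35.6 and 299 ± 66.1 CPM (SD, n = 8 and 5) and did not pass (0.71, SE 0.20, edgeR adjusted p = 0.0926), with all 5 animals above all vehicle animals. Ehhadh (0.50, adjusted p = 0.367), Cyp3a23-3a1 (0.32, 0.849), Nqo1 (0.98, 0.327), Fasn (0.12, 0.934), Cyp7a1 (-0.21, 0.952), Cdkn1a (-0.66, 0.829) and Cyp1a1 (-1.21, 0.543) did not pass in edgeR either, but without r92 Cyp1a1 passed at -3.38, and Cyp7a1 ran from -2.79 without r92 to 0.69 without r56.

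Of the 12 called probes in female liver, the log2 fold changes were 2.00 for Orm1 (edgeR adjusted p = 0.00385), 1.73 for App (1.53e-05), -0.95 for Apoa1 (0.0401) and -3.39 for Noc2l (3e-07). Of 17 acute phase and complement probes 1 rose and 16 did not pass (8 rose and 1 fell when adjusted over the list alone), with camera adjusted p = 7.51e-05, and adjusted p = 0.156 with an estimated correlation. Of 16 cholesterol synthesis and uptake probes 0 passed (4 rose when adjusted over the list alone), with camera adjusted p = 0.00626, and adjusted p = 0.579 with an estimated correlation. Within the last block 0 probes were called in edgeR, 83 had an unadjusted p under 0.05, and the values were 1.93 for Orm1, 0.11 for App, -0.47 for Apoa1 and 0.13 for Noc2l. DESeq2 called 37 probes against vehicle in this set. Leaving out r94 left 3 calls, with Orm1 at 0.98, and leaving out r92 gave 73. The call of Apoa1 ended without any 1 of 7 animals (r50, r51, r54, r55, r94, r95 or r96).

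In male kidney, fatty acid oxidation and lipid synthesis genes rose at 100 mg/kg/day. Ehhadh rose from 112 ± 36.8 CPM (SD, n = 8) to 543 ± 312 CPM (SD, n = 5). Scd, the desaturase that makes monounsaturated fatty acids, rose from 19.9 ± 12.6 to 118 ± 63.5 CPM (SD, n = 8 and 5). All 5 animals lay above all 8 vehicle animals for both. Of 31 probes for PPAR-alpha targets 15 rose, 0 fell and 16 did not pass (20 rose when adjusted over the list alone), with camera adjusted p = 7.56e-30, and adjusted p = 0.000775 with an estimated correlation. Of 14 lipogenesis probes 3 rose (5 when adjusted over the list alone), with camera adjusted p = 2.91e-06, and adjusted p = 0.000775 with an estimated correlation. Of 15 cholesterol synthesis and uptake probes 4 rose (6 when adjusted over the list alone), with camera adjusted p = 1.01e-10, and adjusted p = 0.0131 with an estimated correlation. Members of these lists were examined further after their values were seen. Among them Insig1, a sterol-responsive protein of the endoplasmic reticulum, stood at 1541 ± 282 and 4450 ± 1829 CPM (SD, n = 8 and 5). Srebf1, the transcription factor of lipid synthesis, stood at 28.9 ± 9.26 and 98.7 ± 36.4 CPM (SD, n = 8 and 5).

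The changes in male kidney were 2.28 (SE 0.27, edgeR adjusted p = 8.71e-08) for Ehhadh, 1.58 (SE 0.18, adjusted p = 8.71e-08) for Eci1 and 1.64 (SE 0.35, adjusted p = 0.00302) for Vnn1, a pantetheinase. Scd rose by 2.55 (SE 0.43, adjusted p = 0.000121), Srebf1 by 1.77 (SE 0.26, adjusted p = 8.74e-06), Insig1 by 1.53 (SE 0.19, adjusted p = 3.04e-07) and Fasn, the fatty acid synthase, by 0.68 (SE 0.19, adjusted p = 0.0412). The 4 probes called inside the last block included Ehhadh (1.94, edgeR adjusted p = 0.00679), Eci1 (1.51, 0.00151) and Hsdl2 (1.00, 0.00355). There Scd stood at 1.73, Srebf1 at 0.96, Insig1 at 0.87, Vnn1 at 1.69 and Fasn at 0.47, none of which passed. At 30 mg/kg/day Ehhadh was 0.29, Eci1 0.05 and Scd 0.74 above vehicle. Kif20a, a mitotic kinesin, fell from 8.28 ± 2.68 to 2.25 ± 1.46 CPM (SD, n = 8 and 5; log2 fold change -1.84, within-block -1.56), and of 24 cell cycle probes it was the 1 that fell (3 when adjusted over the list alone; camera adjusted p = 0.00155, and adjusted p = 0.131 with an estimated correlation). Inflammatory cytokines (camera adjusted p = 0.00391), interferon response (0.00885) and fibroblast genes (0.000165) were lower as lists without a passing member, with adjusted p = 0.31, 0.562 and 0.31 with an estimated correlation. Tnnc2, a troponin of fast skeletal muscle, fell from 428 ± 75.6 to 29.6 ± 21.7 CPM (SD, n = 8 and 5; -3.86), but within the block it stood at 0.62. The count of 39 was 23 without r44 and 24 without r45, and with vehicle and 100 mg/kg/day libraries alone 17 probes were called. The call of Fasn ended without any 1 of 9 animals (r01, r02, r04 to r07, r44, r45 or r48) and that of Kif20a without r45, r46 or r47.

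In female kidney, genes of cell division rose against vehicle at 100 mg/kg/day. Mki67, a marker of dividing cells, rose from 35.6 ± 5.17 to 59.2 ± 10.8 CPM (SD, n = 8 and 5), with all 5 animals above all vehicle animals. Gins1, a part of the replication helicase, rose from 11.9 ± 4.22 to 25.9 ± 6.94 CPM (SD, n = 8 and 5), Ube2t, a ubiquitin-conjugating enzyme of DNA repair, from 2.97 ± 1.39 to 11.1 ± 3.29 CPM (SD, n = 8 and 5) and the cyclin Ccna2 from 11.2 ± 4.59 to 21.5 ± 3.64 CPM (SD, n = 8 and 5). Igfbp3, a binding protein of insulin-like growth factor, fell from 675 ± 228 to 297 ± 93.5 CPM (SD, n = 8 and 5). Of 27 cell cycle probes 8 rose, 0 fell and 19 did not pass (13 rose when adjusted over the list alone), with camera adjusted p = 9.73e-08, and adjusted p = 0.0306 with an estimated correlation. Of 15 cholesterol probes 3 rose, Msmo1, Tm7sf2 and Fdps (also 3 when adjusted over the list alone), with camera adjusted p = 0.00753, and adjusted p = 0.409 with an estimated correlation.

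The log2 fold changes in female kidney were 0.73 (edgeR adjusted p = 0.00679) for Mki67, 1.11 (0.00268) for Gins1, 1.88 (0.00034) for Ube2t, 0.94 (0.0132) for Ccna2 and -1.18 (0.0219) for Igfbp3. The largest rises were in the potassium channel gene Kcnd2 (2.36), Agmo (2.34), the glycolytic enzyme Pkm (2.16), LOC100360856 (2.14), the amylase Amy2a3 (2.14), the receptor Klra17 (2.03) and Ms4a6bl (1.96). Zfp354a (-0.97), Cyp2b1 (-0.75), Lgals8 (-0.60), Oxct1 (-0.47), Birc2 (-0.42) and Itfg1 (-0.38) fell. Within the last block edgeR called 0 probes, and 66 of 2262 tested had an unadjusted p under 0.05. Kcnd2 stood there at -0.12, Agmo at -0.01, Pkm at -0.27, LOC100360856 at 0.18, Amy2a3 at 0.03, Klra17 at 0.44, Ms4a6bl at -0.05, Mki67 at 0.36, Gins1 at 0.27, Ube2t at 0.71, Ccna2 at 0.16 and Igfbp3 at -0.79. The count fell from 143 to 45 without r94 and to 60 without r95, and to 40 with vehicle and 100 mg/kg/day libraries alone. Without r95, Mki67 stood at 0.59 and Ccna2 at 0.87, and neither passed. Igfbp3, Cyp2b1 and Itfg1 lost their calls without r94 or r95, Birc2 without r93 or r96, Tm7sf2 without any 1 of 4 animals, Lgals8 of 6, Msmo1 of 7, Oxct1 of 8, Zfp354a of 9 and Fdps of 10.

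In male spleen, transcripts of dividing cells and of the liver were lower at 100 mg/kg/day than in vehicle animals. Mki67 fell from 400 ± 167 to 175 ± 51 CPM (SD, n = 8 and 5), with 4 of 5 animals below all vehicle animals. Ccnf, a cyclin, fell from 23.4 ± 5.89 to 10.6 ± 2.69 CPM (SD, n = 8 and 5), and Zwilch, a part of the kinetochore, from 8.83 ± 2.88 to 3 ± 0.951 CPM (SD, n = 8 and 5). Apoa1 fell from 602 ± 136 to 211 ± 14.3 CPM (SD, n = 8 and 5), and prothrombin F2 from 79 ± 13.8 to 31.3 ± 1.93 CPM (SD, n = 8 and 5), with all 5 animals below all 8 vehicle animals. Of 32 cell cycle probes 14 fell, 0 rose and 18 did not pass (20 fell when adjusted over the list alone), with camera adjusted p = 2.39e-06, and adjusted p = 0.448 with an estimated correlation. Of 13 hepatocyte marker probes 8 fell and 1 rose (8 and 1 when adjusted over the list alone), with camera adjusted p = 7.8e-06, and adjusted p = 0.376 with an estimated correlation. The rise was in Cps1, from 8.68 ± 3.9 to 39.5 ± 11.1 CPM (SD, n = 8 and 5), which was already 2.43 above vehicle at 0.01 mg/kg/day.

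In edgeR the log2 fold changes in male spleen were -1.19 (SE 0.27, adjusted p = 0.00347) for Mki67, -1.15 (SE 0.24, adjusted p = 0.00185) for Ccnf, -1.22 (SE 0.30, adjusted p = 0.00568) for the spindle gene Nusap1 and -1.54 (SE 0.35, adjusted p = 0.00332) for Zwilch. Apoa1 changed by -1.51 (SE 0.15, adjusted p = 5.93e-10) and F2 by -1.33 (SE 0.15, adjusted p = 1.96e-08). Ahsg (-1.40), Plg (-1.41), Fabp2 (-1.41), Fgf13 (-1.36), the melatonin receptor Mtnr1b (-1.61) and aromatase Cyp19a1 (-1.71) fell as well. Cebpd, a transcription factor of inflammation, rose by 0.86 from 135 ± 21.2 to 245 ± 40.9 CPM (SD, n = 8 and 5). Arhgdib (0.94), Cd97 (0.80), Arhgap30 (0.72), Dennd2d (0.72), LOC100910669 (1.16) and Pik3c2a (0.83) rose as well. Inside the last block Mki67 stood at -0.64, Ccnf at -0.34, Nusap1 at -0.79, Zwilch at -1.31, Apoa1 at -0.05, F2 at -0.12, Ahsg at 0.04, Plg at 0.04, Cps1 at -0.05 and Cebpd at 0.59, and none passed. Of the cell cycle probes 3 were lower there at an unadjusted p under 0.05, and of the hepatocyte probes 0. The 3 probes called inside the block were pancreatic transcripts, chosen after their values were seen, namely Amy2a3 (-5.85), Spink3 (-4.54) and Spink1 (-2.45). The count of 406 fell to 264 without r44, to 226 without r48 and to 155 with vehicle and 100 mg/kg/day libraries alone, and the call of LOC100910669 ended without any 1 of 9 animals.

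Liver transcripts were lower in male testis too at 100 mg/kg/day. Of 13 hepatocyte marker probes 8 fell and 1 rose (9 and 1 when adjusted over the list alone), with camera adjusted p = 2.55e-16, and adjusted p = 0.00193 with an estimated correlation. Apoa1 fell from 1894 ± 328 CPM (SD, n = 7) to 614 ± 34 CPM (SD, n = 4) and Ahsg from 250 ± 47.5 to 62.1 ± 9.94 CPM (SD, n = 7 and 4), both examined after their values were seen. Cps1 rose from 4 ± 3.4 to 16.6 ± 7.38 CPM (SD, n = 7 and 4). The sulfotransferases Sult1c2 (-2.81) and Sult2a2 (-3.01) fell, and Svs5, a seminal vesicle protein, rose (1.32), though without r48 it stood at 0.82, and its call ended without any 1 of 6 animals. Acute phase probes (5 of 15 lower, 6 when adjusted over the list alone; camera adjusted p = 1.84e-05, and adjusted p = 0.0567 with an estimated correlation), thyroid hormone probes (2 of 6 lower; 0.00262, and adjusted p = 0.0771 with an estimated correlation) and skeletal muscle probes (2 of 10 lower; 0.00218, and adjusted p = 0.448 with an estimated correlation) were lower too. In edgeR Apoa1 changed by -1.62 (SE 0.12, adjusted p = 7.99e-14), Ahsg by -2 (SE 0.18, adjusted p = 7.2e-11) and Cps1 by 2.07 (SE 0.35, adjusted p = 4.53e-05). Within the block they stood at 0.05, -0.32 and 0.00, Sult1c2 at -0.95, Sult2a2 at -1.85 and Svs5 at -0.02. There 0 probes were called in edgeR and 109 had an unadjusted p under 0.05. The count of 104 in male testis was 69 without r44, and keeping all libraries gave 230.

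**Figure D3:**
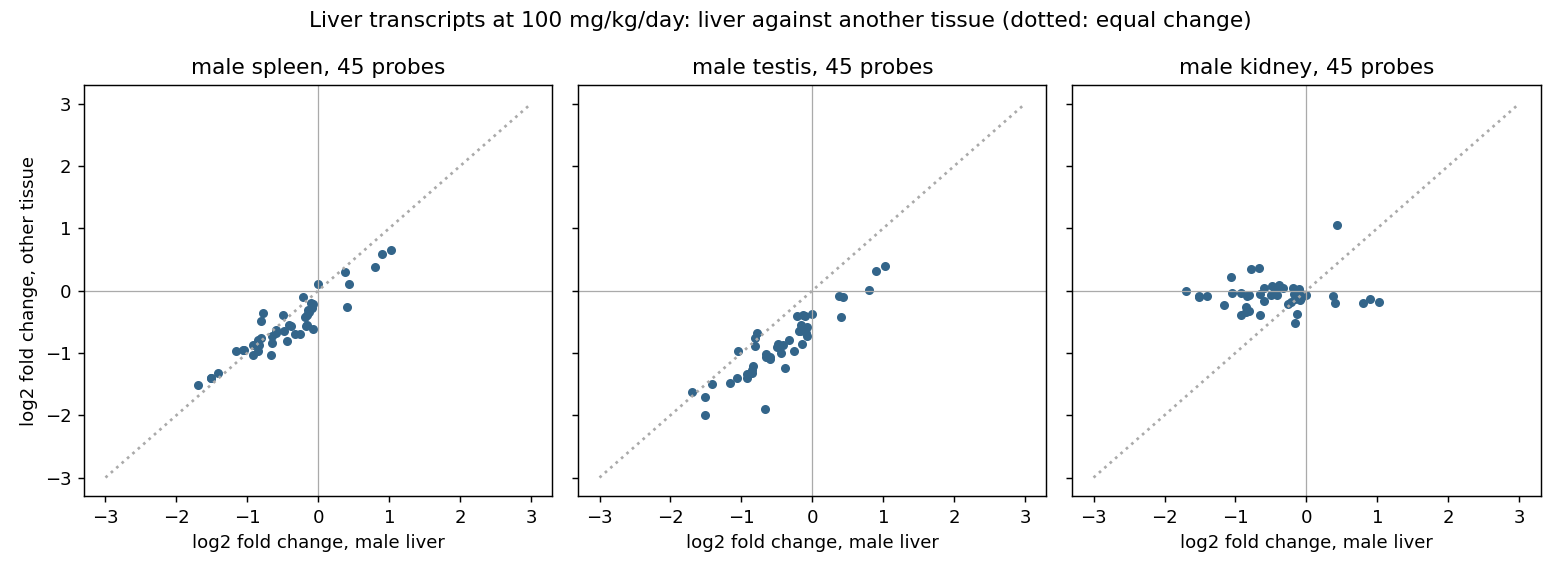
Log2 fold change at 100 mg/kg/day against vehicle of 45 liver transcripts in male liver (horizontal axis) and in male spleen, testis or kidney (vertical axis), with a point for each transcript and a dotted line of equal change. The points follow the line in spleen (Pearson r = 0.935 across transcripts) and testis (0.908) and not in kidney (0.0573); transcripts are not independent replicates.

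In female thyroid, transcripts of macrophages, granulocytes and inflammation rose at 100 mg/kg/day. Il1b, the cytokine interleukin 1 beta, rose from 40.8 ± 14 CPM (SD, n = 8) to 912 ± 1628 CPM (SD, n = 5), with 3 of 5 animals above all vehicle animals. Fosl1, a subunit of the transcription factor AP-1, went from 10.8 ± 3.12 to 248 ± 510 CPM (SD, n = 8 and 5). Genes examined after their values were seen were the metalloproteinase inhibitor Timp1, at 510 ± 181 and 6168 ± 7138 CPM (SD, n = 8 and 5), and the macrophage gene Cd68, at 126 ± 50.9 and 443 ± 414 CPM (SD, n = 8 and 5). Cyp2b1 and Cyp2b2 fell from 346 ± 530 to 31.6 ± 10.2 CPM and from 142 ± 212 to 13.8 ± 5.71 CPM (SD, n = 8 and 5). Of 12 macrophage and granulocyte probes 7 rose and 5 did not pass (8 rose when adjusted over the list alone), with camera adjusted p = 1.14e-06, and adjusted p = 0.42 with an estimated correlation. Of 22 inflammatory probes 6 rose (9 when adjusted over the list alone; camera adjusted p = 0.00867, and adjusted p = 0.462 with an estimated correlation). Thyroglobulin (Tg), the main transcript of thyroid follicle cells, was at 9.77 and 12.4 log2 CPM in r94 and r95 and between 13.6 and 15.3 in vehicle animals, so it moved against these lists in those libraries.

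The log2 fold changes in female thyroid were 4.47 (SE 0.64, edgeR adjusted p = 1.15e-05) for Il1b, 4.51 (SE 0.87, adjusted p = 0.00118) for Fosl1, 3.59 (SE 0.43, adjusted p = 2.25e-07) for Timp1 and 1.80 (SE 0.35, adjusted p = 0.00118) for Cd68. Chosen after seeing their values, the chemokine Ccl3 (3.74), osteopontin Spp1 (3.98), S100a9 of granulocytes (2.98), the adaptor Tyrobp (2.26) and lysozyme Lyz2 (0.77) rose. Aldh1a1 (-2.83), chosen likewise, fell, as did Cyp2b1 (-3.45) and Cyp2b2 (-3.36). Inside the last block 18 probes were called in edgeR, 16 higher and 2 lower, among them Il1b (4.13), Timp1 (3.19), Ccl3 (4.76), Cd68 (2.19), Tyrobp (2.07) and Lyz2 (1.26). Smaller shifts were seen in cholesterol (3 of 16 higher; camera adjusted p = 0.0299, and adjusted p = 0.555 with an estimated correlation), kidney tubule injury (3 of 12 higher, among them Timp1 and Spp1, which many cell types express; 0.0289, and adjusted p = 0.505 with an estimated correlation), cell cycle (1 of 31 higher; 0.00867, and adjusted p = 0.555 with an estimated correlation) and CAR and PXR targets (3 of 18 lower; 0.0198, and adjusted p = 0.484 with an estimated correlation). Thyroid hormone genes (0.00516), adipocyte genes (0.0158) and PPAR-alpha targets (0.0299) were lower in camera with 0 members passing, and adjusted p = 0.42, 0.555 and 0.555 with an estimated correlation. Without r94 the count fell from 110 to 5, with Il1b at 2.19, Fosl1 at 0.87, Ccl3 at 0.61, S100a9 at 0.60, Spp1 at 2.50 and Cd68 at 1.1. The calls of Cyp2b2 and Aldh1a1 ended without r49, r54, r94 or r95, that of Cyp2b1 without any 1 of 7 animals and that of Lyz2 of 9. The count was 62 without r50, 61 without r53 and 39 without r95, and with vehicle and 100 mg/kg/day libraries alone 0 probes were called in edgeR.

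**Figure D4:**
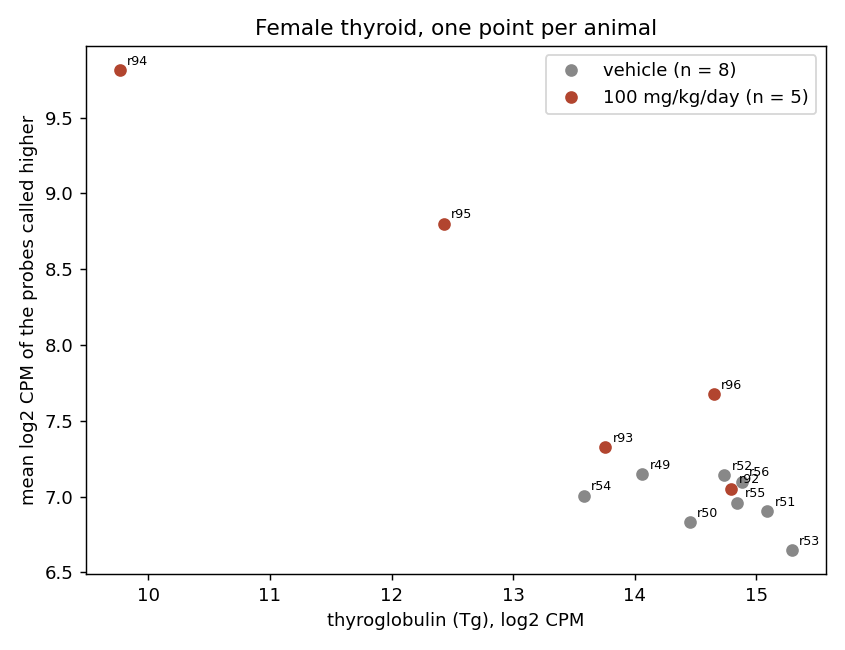
Mean level of the 103 probes called higher (log2 CPM, vertical axis) against the level of thyroglobulin (log2 CPM, horizontal axis) in female thyroid, with a point for each of 8 vehicle animals (grey) and 5 animals at 100 mg/kg/day (red). Animals r94 and r95 stand at 9.81 and 8.80 on the vertical axis, above the vehicle range of 6.65 to 7.15, and at 9.77 and 12.4 on the horizontal axis.

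The remaining sets each had few called probes at 100 mg/kg/day. In male lung Acvrl1, an endothelial receptor of the TGF-beta family, rose from 1102 ± 223 to 1900 ± 353 CPM (SD, n = 8 and 5; log2 fold change 0.79, edgeR adjusted p = 0.000548, within-block 0.71), and the myosin Myh2 rose (0.83, within-block -0.24). In male heart Myh7, the slow myosin heavy chain, was the 1 called probe, at 1182 ± 189 and 3906 ± 1786 CPM (SD, n = 7 and 4; 1.72, adjusted p = 0.0285, within-block 0.94). In female uterus Myh7 rose from 32.6 ± 4.73 to 131 ± 17 CPM (SD, n = 8 and 5; 2.01, within-block 0.28), as did App (1.85), Fstl1 (1.30) and Tg (0.92), the last 2 examined after their values were seen, while Noc2l fell (-2.68). In female adrenal gland LOC688090 fell from 46.7 ± 82.5 to 0.0872 ± 0.195 CPM (SD, n = 8 and 5; -8.12, adjusted p = 0.0152) and was also called within the block (-8.79, edgeR adjusted p = 0.0133). The synaptic gene Snap25 fell there (-0.82) and Cyp2e1 rose (2.31), though without r94 Cyp2e1 stood at 0.03. In female thymus the muscle protein Csrp3 rose (3.39, within-block 1.73) and Zfp367 fell (-0.93, within-block -0.15). In female ovary Igfbp1 fell (-4.67), but it stood at -0.12 without the vehicle animal r49. In female brain F5 rose (4.08), but it stood at -0.66 without r94. Serpinf1 fell in male thyroid (-1.04), an observation made after its values were seen. Leaving out 1 animal also ended the calls of Myh2 in male lung (any of 8 animals), Myh7 in male heart (any of 7), Tg in female uterus (any of 8), LOC688090 (any of 5) and Cyp2e1 (any of 7) in female adrenal gland, Igfbp1 in ovary (any of 6) and Serpinf1 (any of 8).

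Among the lists in these sets, skeletal muscle genes rose in female lung (1 of 10 passing, 7 when adjusted over the list alone) with camera adjusted p = 4.09e-10, and adjusted p = 0.000378 with an estimated correlation, but 0 members were higher within the block. Kidney tubule injury genes were lower in female ovary (0 of 13 passing) with camera adjusted p = 0.000171, and adjusted p = 0.00456 with an estimated correlation, and 5 were lower within the block at an unadjusted p under 0.05. Fibroblast and matrix genes were lower in male thyroid (1 of 15 passing, 11 when adjusted over the list alone) with camera adjusted p = 3.59e-15, and adjusted p = 0.0703 with an estimated correlation. Of the other lists, camera called 6 in female adrenal gland, 6 in female brain, 6 in female uterus, 4 in female thymus, 3 in female ovary, 4 in male thymus, 3 in male brain and 2 in male lung, and with an estimated correlation 0 of these were called. In female heart, female spleen, male adrenal gland and male heart camera called 0 lists.

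Some probes changed in many tissues at once. Col3a1, a collagen of connective tissue, fell in 8 sets, from -4.11 to -2.19 on the log2 scale, and in male lung it went from 11096 ± 1762 to 757 ± 199 CPM (SD, n = 8 and 5; edgeR adjusted p = 6.6e-15). Tnnc2 fell in 5 male sets and rose in 3 female sets, between -4.65 and 1.96, and in male lung it fell from 560 ± 93.7 to 41.6 ± 11.4 CPM (SD, n = 8 and 5). Daxx, a histone chaperone, fell in 5 male sets and rose in 3 female sets, between -1.78 and 1.59. Noc2l fell in 5 sets, App rose in 4, Fstl1, a secreted glycoprotein, rose in 4 and fell in 1, Sec24d, a coat protein of secretory vesicles, rose in 4, and Ttr, the carrier of thyroid hormone, rose in 1 and fell in 4. Between 100 and 30 mg/kg/day inside the last block an unadjusted p under 0.05 was reached in 0 of the 8 sets for Col3a1 and for Tnnc2, in 1 of 8 for Daxx, in 1 of 5 for Noc2l (female heart, where it was higher), in 0 of 4 for App and for Sec24d, in 0 of 5 for Ttr and in 2 of 5 for Fstl1. For Col3a1, female lung lost the call without r93 (-2.25), and calls ended also for Tnnc2 in male brain (without any 1 of 7 animals), Daxx in female brain (of 9) and male thyroid (of 5), Noc2l in female heart (of 8) and Apoa1 in female spleen (of 6). In male lung Col3a1 was already at -2.18 at 0.01 mg/kg/day, and Tnnc2 was at 0.01, -1.30 and -2.47 at 0.01, 10 and 30 mg/kg/day.

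The lower doses were compared with vehicle in the same fits to describe the dose course. Of the PPAR-alpha genes that rose in male liver at 100 mg/kg/day, Cyp4a1 lay between -0.50 and 0.19 and Ehhadh between -0.12 and 0.35 below 30 mg/kg/day, and neither passed in edgeR there. Counts of called probes followed another course. Over the 11 female sets edgeR called 191, 107, 102, 140, 64, 1480 and 138 probes at 0.01, 0.1, 0.3, 1, 3, 10 and 30 mg/kg/day. Over the 10 male sets it called 208, 252, 607, 213, 57, 222 and 232. Each female set had between 42 and 351 calls at 10 mg/kg/day, with the most in female kidney, and each of the 5 animals of that dose lay in block 5. In males the most calls below 100 mg/kg/day were the 306 in spleen at 0.3 mg/kg/day, which fell to 202 without r19 and to 173 without r22. Inside block 5, where 10 and 30 mg/kg/day animals could be compared, 5 probes were called over the 11 female sets. In 4 comparisons edgeR called 0 probes. These were female liver at 3 mg/kg/day (83 at an unadjusted p under 0.05, 1 in DESeq2), female thyroid at 3 mg/kg/day (151 and 5) and at 30 mg/kg/day (64 and 1), and male heart at 30 mg/kg/day (95 and 0).

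**Figure D5:**
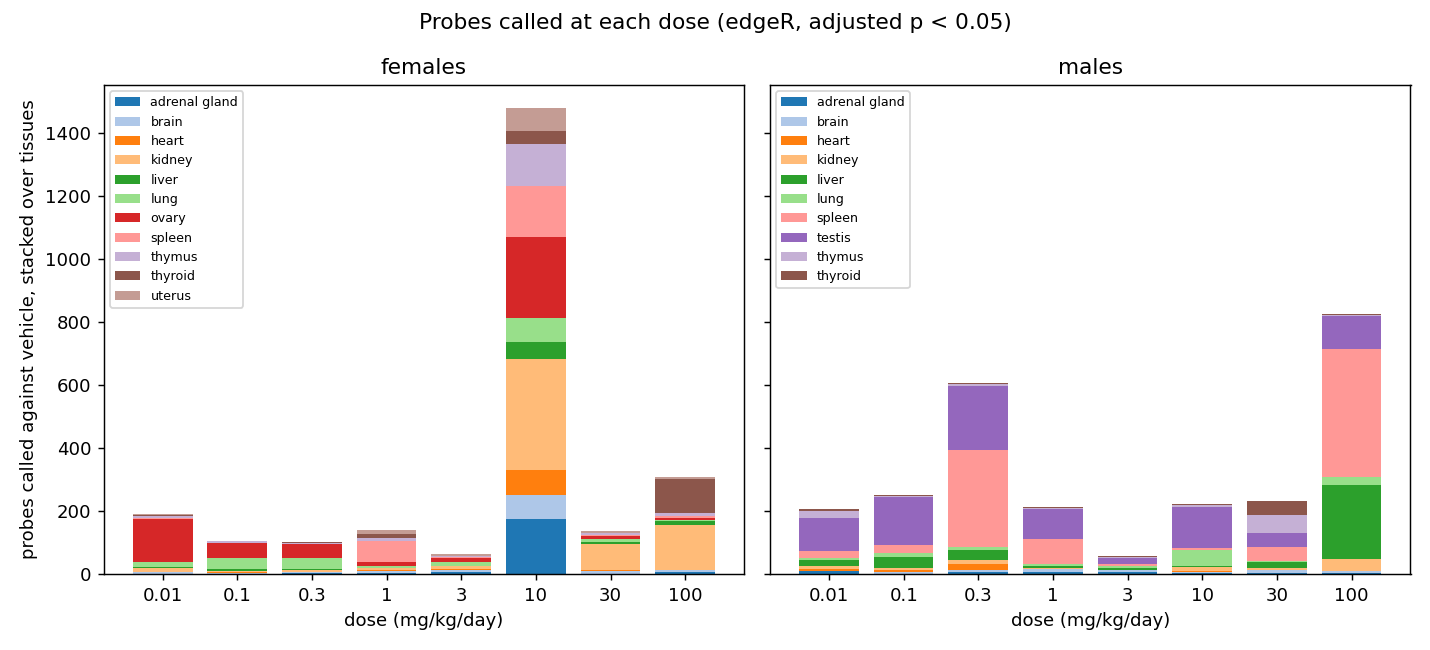
Probes called in edgeR at an adjusted p under 0.05 at each dose (mg/kg/day) against vehicle, stacked over tissues, for females and for males. The tallest female bar is that of 10 mg/kg/day, with 1480 calls over 11 sets, against 64 at 3 and 138 at 30 mg/kg/day.

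Benchmark doses, at which a fitted curve departs by 1 SD from its value at no dose, were computed for a transcriptomic point of departure. The PPAR-alpha targets in male liver had a median benchmark dose of 27.5 mg/kg/day over 10 kept probes, ranging from 15.5 to 59, and all 10 also differed inside the last block at an unadjusted p under 0.05. The CAR and PXR targets there had a median of 37.7 mg/kg/day over 7 probes, of which 3 differed within the block. In male kidney the PPAR-alpha targets had a median of 60.2 mg/kg/day over 9 probes, of which 8 differed within the block. In female thyroid the medians were 69 mg/kg/day for inflammatory genes, 80.4 for macrophage genes and 60.7 for cholesterol genes. Cell cycle genes had a median of 46.1 mg/kg/day in male spleen (1 of 7 probes differed within the block) and 47 in female kidney (0 of 4). The lowest list medians were those of hepatocyte markers, 2.44 mg/kg/day in male spleen and 2.54 in male liver, followed by sex-biased liver genes (2.56) and CAR and PXR targets (3.49) in female kidney and acute phase genes in male spleen (12.8). None of the hepatocyte probes, and none of the CAR and PXR probes in female kidney, differed within the block.

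Over all kept probes of a set the median benchmark dose was 32.3 mg/kg/day in male liver (95% interval 25.9 to 42.2, 39 probes), 43.2 in male kidney (29.6 to 60.2, 22 probes), 39.8 in male spleen (16.4 to 42.7, 49 probes), 7.69 in female kidney (4.96 to 12.2, 92 probes) and 70.1 in female thyroid (66.1 to 76.2, 60 probes). Intervals were wide for 46.2 in female thymus (4.33 to 64.1, 30 probes), 36.7 in female liver (1.62 to 77.5, 11 probes), 74.3 in female ovary (15.4 to 88.1, 10 probes), 1.19 in female adrenal gland (0.00708 to 56.1, 10 probes) and 0.134 in male testis (0.00243 to 16, 11 probes). The other 11 sets kept fewer than 10 probes and have no median. With a benchmark response of 2 SD the medians were 64.1 in male liver, 80.4 in male kidney, 84.9 in male spleen and, for the median benchmark dose, female kidney, 81.5. Female thyroid kept 7 probes at 2 SD, too few for a median. With all libraries kept that of male testis was 77.4. Leaving out 1 animal moved the male spleen median to 8.01 without r44, 8.08 without r48, 13.2 without r47 and 15 without r45. It moved that of female kidney to 4.20 without r94 and 4.38 without r95, and that of female thymus to 4.54 without r94 and 21.1 without r92. For the median benchmark dose, female adrenal gland gave 3.35 without r52, 2.68 without r53, 3.29 without r92, 3.31 without r93, 38.6 without r95 and 35.2 without r96, and female liver gave 11.8 without r55. For the median benchmark dose, male testis gave 0.00701 without r04, 0.00903 without r05, 0.0663 without r08, 0.00408 without r46 and 0.00411 without r48.

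The change at 100 mg/kg/day was compared between the sexes in each of the 9 shared tissues. In liver Cyp2c6v1, a cytochrome P450, rose in males from 2260 ± 655 to 9286 ± 3008 CPM (SD, n = 8 and 5) and stood in females at 6122 ± 2117 and 5413 ± 1420 CPM (SD, n = 8 and 5). The female minus male difference in log2 fold change was -2.20 (edgeR adjusted p = 0.000522). Slc17a3, a renal and hepatic phosphate and urate transporter, stood in males at 285 ± 33.9 and 128 ± 41.8 CPM and in females at 308 ± 46.6 and 376 ± 54.6 CPM (SD, n = 8 and 5 for each), a difference of 1.47 (adjusted p = 0.000522). In kidney Mki67 stood in males at 66.1 ± 12.4 and 45.7 ± 7.2 CPM and in females at 35.6 ± 5.17 and 59.2 ± 10.8 CPM (SD, n = 8 and 5 for each), a difference of 1.25 (adjusted p = 0.00342). Cenpw, a centromere protein, moved alike with a difference of 2.07 (adjusted p = 0.00362). In spleen the difference for F2 was 1.59 (adjusted p = 1.84e-05). Ttr in adrenal gland went from 215 ± 33.1 to 32.4 ± 15.5 CPM in males and from 20.8 ± 4.28 to 87.4 ± 9.28 CPM in females (SD, n = 8 and 5 for each), a difference of 4.80 (adjusted p = 1.23e-11).

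By tissue, the change differed between the sexes for 213 probes in liver (115 higher in females, 98 lower), 105 in spleen (74 and 31), 63 in kidney (48 and 15), 37 in lung (28 and 9), 22 in thymus (13 and 9), 5 in adrenal gland (4 and 1), 3 in brain (3 and 0) and 3 in thyroid (1 and 2), by edgeR. In heart the count was 0, with 106 at an unadjusted p under 0.05 and 0 in DESeq2. Each sex was compared with its own block 1, so these differences carry the same limit. Sex also goes with the library prefix, so batch and sex cannot be told apart. Inside the last block the difference between the sexes was called for 3 probes in lung and for 0 in each of the other tissues. Leaving out 1 animal moved the count in liver to 135 without r44, 360 without r92, 141 without r94 and 131 without r96, that in kidney to as few as 31 without r95, that in spleen to as few as 13 without r93, that in lung to 6 without r45 and that in thymus to 2 without r47 and 87 without r96. DESeq2 gave 71 in lung, 51 in thymus and 29 in thyroid.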

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

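The tests of blocks, of depth and of tissue makeup below, and those of hepatocytes and of a separate response of spleen or testis, were chosen after the results were seen; the match of spleen and testis to an animal's own liver and the counts over other splits, except those for male liver and for the sexes in liver at 100 mg/kg/day, were not.

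In female rats 1480 probes were called at 10 mg/kg/day over 11 sets, against 64 at 3 and 138 at 30 mg/kg/day. Thinning the vehicle and 10 mg/kg/day libraries of each set to the lowest total among them gave 1266 calls, 85.5% as many, which argues against low depth as the whole cause. Inside block 5, where 10 and 30 mg/kg/day animals lie together, the called probes held a median over sets of 0.258 of their change against vehicle (0.0475 to 0.613), so a difference between blocks may account for most of it. At 30 mg/kg/day the animals of block 5 differed from those of block 6 in the same direction, by a median of 0.253 (heart) to 0.758 (adrenal gland) of that change, which argues against a response absent at 30 mg/kg/day as the whole cause. Whether such a response adds to it cannot be told apart, as only 2 animals at 30 mg/kg/day lie in block 5.

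Liver transcripts were lower in male spleen and testis at 100 mg/kg/day, with 24 of 45 called lower and 2 higher in spleen, and 29 lower and 1 higher in testis. Across these transcripts the changes followed those in liver, with Pearson r = 0.935 in spleen and 0.908 in testis (0.233 and 0.144 over other probes; transcripts are not independent replicates), which argues against a response of spleen or testis cells unlike that of the liver. The level in vehicle spleen differed by 1.37-fold between the highest and lowest animal, which argues against hepatocytes cut out with the spleen. Liver transcripts of a spleen library followed the animal's own liver library within dose groups more than those of others. The permutation p was 0.0001, the least possible with 10000 (0.00038 adjusted over 19 sets). Carry-over from liver RNA or libraries, at 1.04% of the liver level, may be a source. So may a shared block, as some dose groups span 2. In testis the test gave a permutation p = 0.0478 (0.101 adjusted), which leaves carry-over open. A response or block shift shared by an animal's tissues stays open in either.

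Inflammatory transcripts rose in female thyroid at 100 mg/kg/day together with a low thyroglobulin in r94 (9.77 log2 CPM) and r95 (12.4), and with the epithelial keratin Krt7 at 13.2 in r94, 8.22 in r95 and 6.72 to 7.63 in vehicle animals. Over 13 vehicle and 100 mg/kg/day libraries the mean of the 103 probes called higher correlated with thyroglobulin at Spearman rho = -0.698 (permutation p = 0.0103) and Pearson r = -0.928 (permutation p = 0.00105), r was -0.351 without the 2 libraries farthest from the median of thyroglobulin, so the relation rests on those, and within the vehicle animals it was -0.458 (permutation p = 0.258, n = 8). A different makeup of the tissue piece in these animals may therefore account for the rise. On these probes, chosen for being higher in the 5 animals, 4 of 5 lay above the highest vehicle animal, which that choice favours, and r92 (7.05) lay inside the vehicle range (6.65 to 7.15), which goes against a rise in every animal. Without r94 the count was 5, against 110.

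For each count of calls 40 splits were fitted, the real one included. Taken 1 at a time, chance can be excluded for 103 counts, where the real split alone gave as many (1 of 40). Over so many counts some reach this by chance. Small ones such as 1 in male heart at 1 mg/kg/day (highest other 0) weigh little. Blocks stay open as a cause, as vehicle animals fill block 1. At 100 mg/kg/day it can be excluded in 11 sets, among them male spleen (406, highest other 221), male liver (234, highest other 13), male testis (104, highest other 29), male kidney (39, highest other 18) and male lung (26, highest other 1). It cannot be excluded in the other 10, which include female kidney (143, highest other 214; 2 of 40), female thyroid (110, highest other 129; 2 of 40), female liver (12, highest other 47; 3 of 40), female lung (2, highest other 3; 4 of 40), male thyroid (3, highest other 65; 10 of 40), female uterus (5, highest other 26; 12 of 40) and male thymus (4, highest other 12; 14 of 40). For the difference between the sexes it can be excluded in 6 tissues (213 in liver, highest other 1) and not in heart (0, highest other 2), brain (3, highest other 188) or adrenal gland (5, highest other 654).

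At lower doses the splits excluded chance for the 306 calls of male spleen at 0.3 mg/kg/day (highest other 210) and for all 11 female counts at 10 mg/kg/day. They did not for male spleen at 0.1 (27, highest other 363; 5 of 40) and 3 mg/kg/day (7, highest other 321; 6 of 40), female uterus at 0.01 (2, highest other 36; 21 of 40), 0.1 (2, highest other 23; 13 of 40), 0.3 (1, highest other 20; 16 of 40) and 30 mg/kg/day (7, highest other 26; 15 of 40), and male thymus at 0.1 (5, highest other 19; 23 of 40), 0.3 (7, highest other 21; 18 of 40) and 1 mg/kg/day (4, highest other 22; 9 of 40). The same holds for female heart at 0.1 mg/kg/day (1, highest other 7; 8 of 40) and for the 4 counts of 0 (40 of 40). Splits that call several times the real count, such as 654 against 5 in the adrenal gland of both sexes or 358 against 13 in female kidney at 0.01 mg/kg/day, point to a structure of the samples other than dose.

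The change at 100 mg/kg/day differed between the sexes, by the interaction test in edgeR and with the female minus male difference in log2 fold change given, for Noc2l (-3.43), Cyp2c6v1 (-2.20) and Slc17a3 (1.47) in liver, Ttr (4.80), Daxx (2.70) and Snap25 (-1.21) in adrenal gland, Daxx (2.68), Cyp11a1 (0.89) and Tnnc2 (4.35) in brain, and Tnnc2 (5.23), Mki67 (1.25) and Cenpw (2.07) in kidney. It also differed for Tnnc2 (5.75), Daxx (2.92) and Amy2a3 (3.06) in lung, Noc2l (-3.14), Fstl1 (2.31) and F2 (1.59) in spleen, Tnnc2 (6.57), Daxx (2.39) and Csrp3 (4.67) in thymus, and Daxx (3.01), Eed (-1.75) and Paqr9 (-1.81) in thyroid. The calls of Eed and Paqr9 each ended without any 1 of 23 animals, that of Tnnc2 in brain without any 1 of 14, that of Cyp11a1 without any 1 of 5 (r44, r46, r47, r93 or r94) and that of Csrp3 without r47 or r48.

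In 22 of 332 groups of animals (6.63%) 1 animal lay far from the others for a named gene, where chance gives about 1 in 20 groups. In log2 CPM, with the nearest other animal in brackets, these were in females LOC688090 in adrenal gland at 100 mg/kg/day (r93 0.64 [0.17]), F5 in brain at 100 (r94 9.72 [3.43]), Klra17 (r51 2.69 [4.26]) and Igfbp3 (r55 7.84 [9.22]) in vehicle kidney, and Cyp2b1 (r54 0.20 [1.88]) and Cyp1a1 (r55 0.83 [2.80]) in vehicle liver. In liver at 100 mg/kg/day r92 stood apart for Cyp3a23-3a1 (7.48 [5.83]) and Cyp7a1 (4.50 [1.38]). The others in females were Col3a1 in lung at 100 (r93 8.77 [9.58]), Igfbp1 in vehicle ovary (r49 10.76 [4.32]), and in spleen Apoa1 (r96 8.73 [8.01]) at 100 and Noc2l in vehicle animals (r52 6.88 [6.27]).

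In males they were, in vehicle liver, Cps1 (r06 8.81 [7.22]) and Cyp2b2 (r07 10.52 [10.08]), and in liver at 100 mg/kg/day Cyp1a1 (r46 3.40 [4.34]), Fgg (r44 13.88 [14.19]) and A2m (r44 2.31 [3.70]). In lung at 100 mg/kg/day it was Tnnc2 (r48 4.58 [5.58]), in spleen F2 (r02 5.72 [6.26]) and Fgf13 (r01 1.91 [3.12]) in vehicle animals and Mtnr1b (r45 3.24 [2.09]) at 100, and in vehicle thymus Tnnc2 (r01 10.57 [7.56]).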

How the results depend on the processing

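The comparison inside the last block, the benchmark medians from probes that differ there and the lower doses without single animals were chosen after the results were seen, and the other settings were not. No paired analysis was possible because no animal was in more than 1 dose group. The fit inside the block was not rerun without single animals, and 42 alternative benchmark medians rested on fewer than 10 probes and are not given. DESeq2 gave no adjusted p for 11 values. For every change below the cause was not tested, except that settings with fewer libraries have less power by construction. Depth limits the low probes, as counts under 5 CPM rest on few reads. Scaling by DESeq2's size factors shifted the median log2 fold change of a set at 100 mg/kg/day by at most 0.0586 (female thymus).

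Of the changes of named genes, 185 had the same direction and side of the threshold under DESeq2's size factors (5 weaker), 177 under DESeq2's Wald test (1 weaker, 1 stronger), 183 without a filter on low counts (7 weaker), 162 with the probes of a gene summed (3 weaker, 1 stronger), 125 with vehicle and 100 mg/kg/day libraries alone (33 weaker) and 41 with all libraries kept (4 weaker). Of the values without single animals 2451 were the same, 288 weaker, 7 stronger and 15 reversed. Inside the last block 26 were the same, 8 stronger, 110 weaker and 46 reversed.

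Between 100 and 30 mg/kg/day inside the last block edgeR called 26 probes in male thyroid, 18 in female thyroid, 7 in male liver, 4 in male kidney, 3 in male spleen, 3 in female lung, 3 in male thymus (Cyp3a2, Obp3 and Rdh7, all lower), 1 in male brain and 1 in female adrenal gland. It called 0 in female brain, heart, kidney, liver, ovary, spleen, thymus and uterus (137, 98, 66, 83, 177, 146, 81 and 146 at an unadjusted p under 0.05) and in male adrenal gland, heart, lung and testis (104, 88, 179 and 109). The difference between the sexes was called for 3 probes in lung and 0 in adrenal gland, brain, kidney, liver, spleen, thymus and thyroid.

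The direction inside the block was opposite to that against vehicle for the following log2 values: in female adrenal gland Ttr -0.0484, in female brain Daxx -0.0451 and Col3a1 0.10, in female heart Noc2l 1.06, in female kidney Kcnd2 -0.12, Agmo -0.0097, Pkm -0.27, Ms4a6bl -0.0513, Itfg1 0.066 and Birc2 0.0017, in female liver Fasn -0.46, Cyp7a1 2.08, Cdkn1a 1.93 and Noc2l 0.13, in female lung Orm1 -3.78, in female ovary App -0.16, in female spleen Apoa1 0.0753, in female thymus Tnnc2 -0.0301 and Col3a1 0.62, in female uterus App -0.51 and Noc2l 0.53. In males the values were: in male adrenal gland Tnnc2 0.24, in male brain Tnnc2 0.80 and Col3a1 0.0742, in male kidney Tnnc2 0.62, in male liver Cps1 -0.35, Cdkn1a -0.0607 and Nqo1 0.29, in male lung Myh2 -0.24, in male spleen Cps1 -0.0484, Ahsg 0.0372 and Plg 0.0392, in male testis Cps1 -0.0031, Svs5 -0.0161 and Apoa1 0.0498, in male thymus Sec24d -0.16 and Tnnc2 0.25, in male thyroid Daxx 0.21. For the difference between the sexes they were: in adrenal gland Snap25 0.15, in brain Daxx -0.22, Cyp11a1 -0.0619 and Tnnc2 -2.24, in kidney Tnnc2 -0.67, in lung Daxx -0.17, in thymus Tnnc2 -0.26, in thyroid Daxx -0.15.

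With vehicle and 100 mg/kg/day libraries alone the counts moved in female brain (6 to 3), female heart (1 to 0), female kidney (143 to 40), female lung (2 to 5), female thyroid (110 to 0), male adrenal gland (3 to 5), male brain (6 to 1), male kidney (39 to 17), male lung (26 to 13), male spleen (406 to 155) and male thyroid (3 to 1). DESeq2's Wald test moved those in female heart (1 to 2), female liver (12 to 37), female lung (2 to 8), female thymus (7 to 21), female uterus (5 to 13), male adrenal gland (3 to 8), male heart (1 to 2) and male thyroid (3 to 13), the sums at 3 mg/kg/day over female (64 to 115) and male sets (57 to 112), and the differences between the sexes in adrenal gland (5 to 9), brain (3 to 6), kidney (63 to 110), lung (37 to 71), spleen (105 to 229), thymus (22 to 51) and thyroid (3 to 29). DESeq2's size factors gave 2 in female heart and 1 for the sexes in thyroid. Without a filter the counts were 2 in female heart, and 66 and 1 for the sexes in lung and thyroid.

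Keeping the libraries with a quality issue gave 35 calls in female spleen, 0 in male heart, 230 in male testis and 110 over the male sets at 10 mg/kg/day. It gave 517 for the probes called at 0.01 mg/kg/day, sum over the male sets, 336 for the probes called at 3 mg/kg/day, sum over the male sets, 407 for the sex difference in the response at 100 mg/kg/day, spleen, and 77.4 mg/kg/day for the median benchmark dose, male testis. With a benchmark response of 2 SD the medians were 64.1 in male liver, 80.4 in male kidney, 84.9 in male spleen and, for the median benchmark dose, female kidney, 81.5 mg/kg/day. All 8 medians computed with DESeq2's size factors, 6 with a fold filter of 2 and 3 from probes that also differed in the block lay inside the 95% interval of the median from all probes.

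With an estimated correlation camera called fewer lists in female adrenal gland (6 to 0), female brain (6 to 0), female kidney (2 to 1), female liver (2 to 0), female ovary (4 to 1), female thymus (4 to 0), female thyroid (9 to 0), female uterus (6 to 0), male brain (3 to 0), male kidney (7 to 3), male liver (4 to 2), male lung (2 to 0), male spleen (2 to 0), male testis (4 to 1), male thymus (4 to 0) and male thyroid (1 to 0).

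Without single animals (the animal left out in brackets) the counts at 100 mg/kg/day ran from 4 (r94) to 10 (r95) in female adrenal gland, 2 (r94) to 8 (r52) in female brain, 45 (r94) to 182 (r92) in female kidney, 3 (r94) to 73 (r92) in female liver, 4 (r51) to 7 (r55) in female spleen, 4 (r92) to 27 (r96) in female thymus, 5 (r94) to 135 (r92) in female thyroid, 4 (r51) to 11 (r49) in female uterus, 3 (r45) to 10 (r02) in male brain, 23 (r44) to 45 (r03) in male kidney, 143 (r44) to 281 (r47) in male liver, 8 (r45) to 30 (r01) in male lung, 226 (r48) to 482 (r08) in male spleen, 69 (r44) to 109 (r47) in male testis, 4 (r04) to 10 (r01) in male thymus, 1 (r03) to 17 (r06) in male thyroid, 0 (r50) to 2 (r52) in female heart, 0 (r01) to 2 (r07) in male heart and 1 (r93) to 5 (r96) in female lung. Counts over 1.5 times away from the full ones were also 60 in female kidney without r95, 4 in female spleen without r92, 62, 61 and 39 in female thyroid without r50, r53 and r95, 8 in female uterus without r95, 10 and 3 in male brain without r08 and r47, 24 in male kidney without r45, 17 and 13 in male lung without r04 and r46, 264 in male spleen without r44, and 8, 12, 6 and 1 in male thyroid without r01, r02, r46 and r47. In female heart 5 further animals ended the call (r51, r54, r55, r94 and r95) and in male heart 6 (r02, r05, r06, r08, r44 and r45), and 3 others gave 2 calls in female heart (r53, r92 and r96).

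The sums ran from 124 (r59) to 197 (r50) over female sets at 0.01, 61 (r74) to 220 (r72) over female sets at 1, 90 (r88) to 155 (r91) over female sets at 30, 86 (r24) to 302 (r08) over male sets at 1, 44 (r31) to 94 (r32) over male sets at 3 and 122 (r36) to 275 (r34) over male sets at 10 mg/kg/day. For male spleen at 0.3 mg/kg/day they ran from 173 (r22) to 416 (r08), with 202 without r19. Others that moved so far were 213 without r73 in females, and 134, 126, 138 and 126 without r03, r04, r05 and r25 in males, all at 1 mg/kg/day. The differences between the sexes (for spleen, the sex difference in the response at 100 mg/kg/day, spleen) ran from 1 (r44) to 4 (r54) in brain, 0 (r01) to 2 (r96) in heart, 31 (r95) to 130 (r48) in kidney, 131 (r96) to 360 (r92) in liver, 6 (r45) to 45 (r44) in lung, 13 (r93) to 178 (r02) in spleen, 2 (r47) to 87 (r96) in thymus and 1 (r01) to 8 (r92) in thyroid. Other counts over 1.5 times away were in kidney 33 (r44), 37 (r45), 41 (r47), 112 (r92), in liver 135 (r44), 141 (r94), in lung 8 (r46), 21 (r51), 22 (r93), 23 (r05, r48), 24 (r06), in spleen 30 (r48), 33 (r44), 37 (r03), 39 (r47), 41 (r50), 45 (r04), 46 (r55), 69 (r92), 166 (r01), 168 (r08), in thymus 2 (r48), 4 (r44), 6 (r46, r92, r95), 7 (r52, r55), 9 (r56), 11 (r02, r51), 13 (r03, r07, r45), 14 (r01, r53, r94), 1 in brain (r46, r47, r93, r94) and 1 in thyroid without any 1 of 19 animals. The median benchmark doses ran from 4.2 (r94) to 9.17 (r92) in female kidney, 63.4 (r96) to 77.9 (r53) in female thyroid, 25.1 (r44) to 34.1 (r47) in male liver and 8.01 (r44) to 39.9 (r07) in male spleen mg/kg/day. The values that turned were, on the log2 scale, F5 in female brain from -0.66 (r94) to 4.50 (r52), Cyp3a23-3a1 in female liver from -0.33 (r92) to 0.48 (r96), Fasn in female liver from -0.0562 (r93) to 0.30 (r56), Cyp7a1 in female liver from -2.79 (r92) to 0.69 (r56), Orm1 in female lung from -0.16 (r95) to 0.27 (r53) and Fasn in male liver from -0.17 (r47) to 0.26 (r45). Of 168 called values of named genes 50 lost the call without some animal. Passing only without 1 animal were, in female liver, Cyp4a1 (0.74 without r92), Cyp1a1 (-3.38 without r92) and Cyp2b1 (without r50, r92, r93, r95 or r96, from 2.50 to 2.77).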

Other observations

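The comparison inside the last block and the genes named here were chosen after the values were seen, and no call inside the block was rerun without single animals.

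In male thyroid 26 probes were called in edgeR at 100 against 30 mg/kg/day inside the last block (2 higher, 24 lower), and some of the lower ones are genes of fat cells. Of the 12 adipocyte probes 0 were higher and 10 lower there at an unadjusted p under 0.05, and the list was not tested inside the block (against vehicle, camera adjusted p = 0.298, and adjusted p = 0.997 with an estimated correlation). Lpl, the lipase that releases fatty acids from lipoproteins, stood at -1.67 (adjusted p = 0.00718), Fabp4, a fatty acid carrier of adipocytes, at -2.13 (0.0244), Pparg, the regulator of adipocyte genes, at -1.99 (0.0244) and Ucp1, the uncoupling protein of brown fat, at -3.81 (0.0244). Against vehicle none of them passed in edgeR. Lpl had 1928 ± 500 CPM (SD, n = 8) in vehicle animals and 1478 ± 554 CPM (SD, n = 5) at 100 mg/kg/day, and Fabp4 had 17356 ± 9820 and 11952 ± 3211 CPM (SD, n = 8 and 5). Pparg had 57.1 ± 28 and 35 ± 8.36 CPM (SD, n = 8 and 5), and Ucp1 had 313 ± 299 and 150 ± 108 CPM (SD, n = 8 and 5). The 3 animals at 30 mg/kg/day thus stood above both other groups for these genes.

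In male spleen the pancreatic genes Amy2a3, an amylase, and the protease inhibitors Spink3 and Spink1 were called lower at 100 than at 30 mg/kg/day inside the last block (-5.85, -4.54 and -2.45; edgeR adjusted p = 1.3e-06, 6.75e-05 and 0.0121), while against vehicle Amy2a3 stood at -0.23 and Spink3 at -0.50, and Spink1 fell (-1.35, a call that ended without any 1 of 8 animals). In female lung LOC688090 (-4.12) and the acute phase genes Lcn2 (-3.02) and Orm1 (-3.78) were called lower inside the block (edgeR adjusted p = 0.0469 for each), and against vehicle they stood at -2.61, -1.12 and 0.05 and did not pass.

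Liver transcripts also followed the animal's own liver library within dose groups in other sets, of 19 tested. The adjusted p was 0.00038, the floor of 10000 permutations, in male and female adrenal gland, male kidney and female spleen. It was 0.000633 in female kidney and 0.00136 in female thymus. Shared blocks may give this too. Across transcripts the change at 100 mg/kg/day correlated with that in liver at r = 0.837 in female spleen and 0.772 in female ovary, and at 0.0573 in male kidney and 0.0551 in female kidney, where transcripts are not independent replicates.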
